A study of Mus musculus with 6 samples.

How the data were processed

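The series measured poly(A) RNA of mouse liver (C57BL/6) by paired-end sequencing, per the labels' protocols, in 6 libraries of 3 groups with 2 libraries each. The control group was replicates 1 and 3, the APAP group replicates 1 and 3, taken 6 h after 400 mg/kg acetaminophen (APAP, paracetamol) given into the peritoneum, and the COS+APAP group replicates 2 and 3, whose mice received 20 mg/kg costunolide (COS, a plant sesquiterpene lactone) 12 h and again 40 min before the same APAP dose. Groups were taken from the titles, the source names and the treatment field of each library. The protocol text gives the pretreatment to the samples numbered 5 and 6, while in accession order those positions hold the libraries titled model, with APAP as their source name and treatment. If the protocol text and not these labels were right, the APAP and COS+APAP labels would be exchanged and every difference between these groups would change its sign. The titles of the COS+APAP libraries also carry the prefix 2, those of the other 4 libraries the prefix 1, so that any batch that goes with the prefix cannot be separated from COS. Nothing in the labels says that the libraries of a group came from separate animals, and the p-values of single genes measure only the spread between these libraries.

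Reads were aligned with HISAT2 2.0 and assembled with StringTie 1.3.0, per the submitters' processing notes. The genome build is not given in the sources used here. Of the 55401 genes in the table, 55141 Ensembl identifiers were also in mouse GENCODE release 21, and 94.2% of these had identical coordinates there. Coordinates are printed as the deposited table gives them. The authors deposited estimated counts per gene and library, per the file headers. The authors also deposited FPKM values, fragments per kilobase of transcript scaled to sequencing depth, for the same genes and libraries, per the file headers. A further 6 columns of values per sample matched no sample of the series. They were looked at during the work, and no value given here was computed from them. The statements on the title prefix were given weight after that look, which added to the doubt whether the acute phase and *Septin2* differences of the COS+APAP libraries come from COS or from a batch. The estimated counts were whole numbers already and entered the tests without change. They totalled 71115112 to 76669799 per library. Small values were most frequent at multiples of 4 (766 to 990 genes per library had a count of 4, and 290 to 350 a count of 3), so a fragment was taken to stand for about 4 counts. Counts and FPKM carried the same measurement, since the ratio of both between control replicates 1 and 3 lay between 0.997 and 1.003 of its median for the middle 90% of 8061 genes. No entry lacked a gene, and 134 genes shared a symbol with an earlier entry. For a symbol in a gene list the entry with the highest mean FPKM was used. Genes with near-identical copies (*Saa1* and *Saa2*, *Mup17*, the Cyp2a, Cyp2c, Cyp3a, Gst, Ugt1a and Serpina3 families, the globins, *Hspa1a* and *Hspa1b*) can share reads, and their values are uncertain to that extent.

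Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 10051 in all. The plan fixed beforehand named limma on log2(FPKM + 1) as the main test, or edgeR if the table held counts. The table held both. Because the table held counts, the test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling of the library totals, two-sided, with 1 model of the 3 groups over all 6 libraries (3 residual degrees of freedom) and Benjamini-Hochberg adjustment over the 10051 genes. Genes with an adjusted p below 0.05 were called changed. Standard errors of log2 fold changes are the log2 fold change divided by the square root of F. With 2 libraries against 2, no exact permutation test of a single gene can give a p below 0.33, and the called genes rest on the spread shared between groups and genes. For a gene listed at 0 in both libraries of a group, the fold is given as a lower bound against 3 fragments over the group, taken as 12 estimated counts. This floor covers counting error alone.

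The 38 gene lists and the comparisons were fixed before the data were examined. The lists covered drug metabolism, stress responses, inflammation, cell death, lipid, glucose, amino acid and bile acid metabolism, mitochondria, secreted proteins, proliferation, the clock, hepatocyte zones, other cell types of liver, neighbouring tissue and sex-linked genes. Lists with at least 4 tested members, 36 of the 38, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the residuals and fry, which asks whether the members of a list move one way on balance without comparing them with other genes, were run beside it. Gene Ontology and KEGG annotations in the deposited table were tested with a one-sided Fisher exact test (SciPy 1.17.1, pandas 2.3.3, Python 3.11.15) for terms of 10 to 300 tested genes, rises and falls apart, against 8645 tested genes with a Gene Ontology annotation and 3909 with a KEGG annotation. The Fisher test treats genes as independent draws, so its p-values measure no spread between libraries. Figures were drawn with matplotlib 3.10.9.

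Genes were named by a fixed rule. It took per comparison the 6 largest rises and 6 largest falls among called genes whose groups did not overlap and whose mean FPKM was at least 5, predicted genes left out. It added up to 2 rises and 2 falls of each list, or the member with the smallest p where none was called, and a fixed panel of genes known from APAP injury. Of the panel, *Ccl2* and *Tnf* lay below the filter and were not tested. For the opposition of effects, the 2 sets of log2 fold changes share the APAP libraries. Their correlation was therefore set beside 100 simulated draws with no effect, and was computed again with a different APAP library in each effect.

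Alternatives fixed in advance were no filter, a mean FPKM of at least 5, a fold threshold of 2, median-ratio, FPKM-total and quantile scaling, limma with a pseudocount of 0.1 (which changes the test, the pseudocount and the scaling together), a robust spread estimate, only the 2 groups compared, a replicate block, and leaving out each library in turn. Limma on log2(FPKM + 1), the planned main test for a table without counts, became an alternative once counts were found. Alternatives chosen after seeing the data were library totals without TMM, counts divided by 4 and DESeq2 1.42.0. Leaving out libraries for the list and opposition counts was chosen then as well. So were opposed counts with a different APAP library in each effect and a fold threshold of 2 for annotation terms.

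The procedure was tested on simulated counts for the 10051 genes with 50 genes changed at each of 4 fold sizes. For APAP against control it recovered 0% at 1.5-fold, 28% at 2-fold, 84% at 4-fold and 94% at 8-fold, with 7 unchanged genes called. For COS+APAP against APAP the shares were 0%, 26%, 78% and 96%, with 10 unchanged genes called. For COS+APAP against control they were 6%, 10%, 82% and 98%, with 4 unchanged genes called. Far fewer genes were changed in the simulation than were called in the data, which makes the adjusted threshold stricter. These shares therefore do not give the recovery in the data. In each simulated comparison camera called the 1 list of 25 genes that had been moved and 0 of the other 35. The moved list had a camera adjusted p of 4.09e-34, 1.38e-44 and 5.76e-37, and of 0.0288, 0.0193 and 0.0255 with an estimated correlation. In the data, by contrast, camera called 0 lists with an estimated correlation (smallest adjusted p = 0.433, 0.541 and 0.397). The simulated lists therefore do not show how often the preset correlation gives false calls for the lists of the data. The term test, run on 500 terms in all, found the enriched term and called 0 of the others.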

Results

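RNA was sequenced from livers of untreated mice (control), of mice 6 h after 400 mg/kg APAP, and of mice given 20 mg/kg COS 12 h and 40 min before the same APAP dose (COS+APAP), with 2 libraries in each of the 3 groups. The libraries held 75430358 and 73169837 estimated counts in control, 73041613 and 76669799 in APAP, and 71115112 and 75136290 in COS+APAP. Between 20658 and 20947 genes had a value above 0, and 9632 to 10153 had an FPKM of at least 1. Libraries of a group correlated more closely across genes (r = 0.956 in control, 0.964 in APAP and 0.968 in COS+APAP on the log2 scale) than libraries of different groups (0.829 to 0.919), where genes are not independent replicates. The first principal component (54.6% of the variance) placed the COS+APAP libraries between control and APAP, and the second (23.9%) set them apart from both. Transcripts of the mitochondrial genome took 12.78% and 16.09% of the counts in control, 8.28% and 7.37% in APAP, and 11.8% and 10.83% in COS+APAP, and *Alb*, the gene of serum albumin, took 6.81% to 10.08%.

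**Figure D1:**
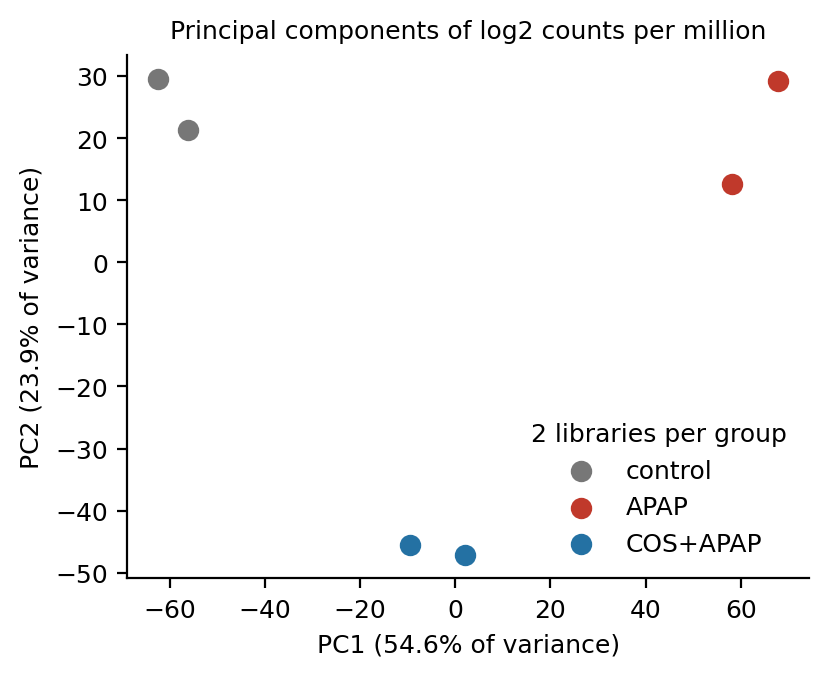
Principal components of log2-transformed, depth-scaled counts of the tested genes, 1 point per library and 2 libraries per group, axes in component scores. The first component (54.6%) ran from control (-56.2 and -62.4) over COS+APAP (-9.5 and 2.1) to APAP (67.9 and 58.1), and on the second (23.9%) the COS+APAP libraries lay at -45.5 and -47.1.

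The comparison of APAP with control asked how the liver's transcripts differed 6 h after the toxic dose. The labels used here record no hour of collection for the control libraries. Whether time of day or feeding differed between these groups was not tested. Of the clock genes, listed as a sign of the hour of collection and feeding, 6 rose and 5 fell, as described later. A difference in time of day or feeding therefore stays open as a part of the differences below. Most immediate early genes and genes of the integrated stress response rose, and most markers of the hepatocytes around the central vein fell. *Hmox1*, which encodes heme oxygenase 1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), rose from 5.315 ± 0.0495 FPKM in control to 730.3 ± 58.3 in APAP (mean ± SD, n = 2), a log2 fold change of 7.24 ± 0.36 (SE) with adjusted p = 0.000878 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as for all genes below. The metallothionein *Mt2* (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) rose from 7.335 ± 2.34 to 2809 ± 145 FPKM (log2 fold change 8.72 ± 0.43, adjusted p = 0.000878). *Cyp7a1*, the rate-limiting enzyme of bile acid synthesis (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), dropped from 33.83 ± 7.23 to 0.73 ± 0.283 FPKM (log2 fold change -5.39 ± 0.47, adjusted p = 0.00153). Of 10051 tested genes 4561 changed, 2342 higher and 2219 lower. Among these, 1211 rose and 1090 fell at least 2-fold.

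Immediate early genes, transcription factors and feedback regulators switched on within hours of a stimulus, had the highest median of the tested lists. Of these, 21 of 27 measured members rose, 0 fell and 6 did not pass (22 and 0 adjusted over the list alone). Immediate early genes had a median log2 fold change of 3.42 (camera adjusted p = 2.5e-08, and adjusted p = 0.452 with an estimated correlation). *Dusp5*, a phosphatase acting on ERK kinases, rose by 7.00, and *Fosl1*, an AP-1 subunit listed at 0 in both control libraries, was at least 238-fold higher (the median stayed at 3.42 with *Fosl1* at that bound). The other large rises outside the lists were the cornified envelope gene *Sprr1a*, at least 236-fold higher, and the microRNA gene *Mir22* (7.78), which can take reads of its host transcript. *Atf3* (8.04) and *Psat1*, an enzyme of serine synthesis (6.36), were among the genes of the ATF4 and integrated stress response, where 19 rose, 1 fell and 3 did not pass (19 and 1 adjusted over the list alone). Genes of the integrated stress response had a median log2 fold change of 1.97 (camera adjusted p = 1.41e-06, and adjusted p = 0.433 with an estimated correlation). The single fall there was *Shmt2* (-1.08), a mitochondrial enzyme of one-carbon metabolism. *Trib3* rose by 2.94. Among the NRF2 targets, which serve antioxidant defence and glutathione synthesis, 15 rose, 4 fell and 10 did not pass (15 and 4 adjusted over the list alone). NRF2 targets had a median log2 fold change of 0.72 (camera adjusted p = 0.0167, and adjusted p = 0.433 with an estimated correlation). *Gclc*, the catalytic subunit of the first enzyme of glutathione synthesis, rose by 2.84, *Txnrd1* by 2.38 and *Nqo1* by 1.13, whereas *Gclm*, the regulatory subunit, stood at -0.88 (adjusted p = 0.3).

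Of the p53 targets 11 rose, 3 fell and 4 did not pass (11 and 4 adjusted over the list alone). p53 targets had a median log2 fold change of 0.63 (camera adjusted p = 0.0473, and adjusted p = 0.433 with an estimated correlation). *Cdkn1a*, an inhibitor of the cell cycle, rose by 8.45, *Btg2* (also an immediate early gene) by 5.87 and the stress cytokine *Gdf15* by 4.88, while *Ccng1* fell by 0.88. In the cell death list 10 rose, 3 fell and 11 did not pass (11 and 3 adjusted over the list alone). Cell death genes had a median log2 fold change of 0.52 (camera adjusted p = 0.0415, and adjusted p = 0.433 with an estimated correlation), with *Tnfrsf12a*, the TWEAK receptor, at 4.81 and *Casp9* at 3.53. Of the autophagy genes 17 rose, 1 fell and 14 did not pass (18 and 2 adjusted over the list alone). Autophagy genes had a median log2 fold change of 0.58 (camera adjusted p = 0.00228, and adjusted p = 0.551 with an estimated correlation), among them the cargo receptor *Sqstm1* (2.56) and the lysosomal protease *Ctsl* (1.97). Of the ribosome biogenesis genes 23 rose, 0 fell and 12 did not pass (25 and 0 adjusted over the list alone). Ribosome biogenesis genes had a median log2 fold change of 0.83 (camera adjusted p = 4.2e-07, and adjusted p = 0.433 with an estimated correlation), and the nucleolar helicase *Ddx21* rose by 1.89. Of the ER chaperones 5 rose, 11 fell and 10 did not pass (6 and 13 adjusted over the list alone). ER chaperones had a median of -0.37 (camera adjusted p = 0.166), with *Hspa5* at 2.19 and *Sdf2l1* at -2.87. Of the heat shock genes 11 rose, 4 fell and 8 did not pass (13 and 4 adjusted over the list alone). Heat shock genes had a median of 0.59 (camera adjusted p = 0.199), where the co-chaperone *Fkbp4* fell by 1.67.

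Among the acute phase proteins, made by hepatocytes in inflammation, 20 rose, 1 fell and 10 did not pass (22 and 1 adjusted over the list alone). Acute phase proteins had a median log2 fold change of 1.21 (camera adjusted p = 1.41e-06, and adjusted p = 0.515 with an estimated correlation). *Lcn2*, a siderophore-binding protein, rose by 4.06. Among the interferon-stimulated genes, known from antiviral responses, 1 rose, 18 fell and 11 did not pass (1 and 19 adjusted over the list alone). Interferon-stimulated genes had a median log2 fold change of -1.15 (camera adjusted p = 6.16e-06, and adjusted p = 0.543 with an estimated correlation), with *Isg15* at -3.07 and *Zbp1* at -2.68. Of the cytokines and chemokines 7 rose, 1 fell and 10 did not pass (7 and 1 adjusted over the list alone). Cytokines and chemokines had a median of 0.11 (camera adjusted p = 0.206), a median that turned negative under other scalings, with *Cxcl1*, a neutrophil attractant, at 4.87 and *Il1b* not past the test at -0.22 (adjusted p = 0.788). Of the other plasma proteins and coagulation factors 15 rose, 5 fell and 20 did not pass (15 and 5 adjusted over the list alone). Plasma proteins and coagulation factors had a median log2 fold change of 0.29 (camera adjusted p = 0.0336, and adjusted p = 0.649 with an estimated correlation), with *F11* at -1.32, and *Alb* did not pass the test (0.52, adjusted p = 0.116).

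Of the cytochrome P450s 4 rose, 16 fell and 9 did not pass (4 and 16 adjusted over the list alone). Cytochrome P450s had a median log2 fold change of -0.92 (camera adjusted p = 0.00237, and adjusted p = 0.551 with an estimated correlation). *Cyp2a5* fell by 3.82, while *Por*, the electron donor of these enzymes, rose by 1.10. *Cyp2e1*, whose enzyme makes the reactive APAP metabolite, went from 2002 ± 506 to 1002 ± 264 FPKM and fell by 0.87 ± 0.27 (adjusted p = 0.0451), a call lost without control replicate 1 or either APAP library (adjusted p up to 0.193) and when libraries were scaled to one FPKM total. Of the glutathione S-transferases 3 rose, 9 fell and 10 did not pass (3 and 9 adjusted over the list alone). Glutathione S-transferases had a median log2 fold change of -0.39 (camera adjusted p = 0.00824, and adjusted p = 0.433 with an estimated correlation), with *Gstm2* at -2.24. Of the glucuronidation and sulfation genes 5 rose, 3 fell and 17 did not pass (5 and 3 adjusted over the list alone). Conjugation genes had a median of -0.18 (camera adjusted p = 0.537), with a mean of 0.03, and camera's direction turned to higher without control replicate 1 (0.813). Among them the estrogen sulfotransferase *Sult1e1* rose by 5.02 and *Papss1*, which makes the sulfate donor, fell by 1.79. Of the bile acid genes 4 rose, 9 fell and 12 did not pass (5 and 9 adjusted over the list alone). Bile acid genes had a median of -0.15 (camera adjusted p = 0.206).

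Among genes of fatty acid oxidation and PPARalpha targets 26 rose, 1 fell and 14 did not pass (26 and 2 adjusted over the list alone). Fatty acid oxidation genes had a median log2 fold change of 0.81 (camera adjusted p = 1.19e-05, and adjusted p = 0.543 with an estimated correlation), with the lipid droplet protein *Cidec* at 6.96 and *Pdk4*, a brake on pyruvate oxidation, at 4.30. Among genes of cholesterol synthesis 0 rose, 18 fell and 8 did not pass (0 and 20 adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of -1.47 (camera adjusted p = 4.2e-07, and adjusted p = 0.452 with an estimated correlation), with *Mvd* at -3.52 and *Fdps* at -2.96. Of the fatty acid synthesis genes 3 rose, 12 fell and 8 did not pass (3 and 13 adjusted over the list alone). Fatty acid synthesis genes had a median log2 fold change of -0.55 (camera adjusted p = 0.0152, and adjusted p = 0.433 with an estimated correlation), with *Thrsp*, a lipogenic regulator, at -4.75. Of the transcripts of the mitochondrial genome 0 rose, 10 fell and 3 did not pass (0 and 11 adjusted over the list alone). Mitochondrially encoded genes had a median log2 fold change of -0.76 (camera adjusted p = 0.00228, and adjusted p = 0.604 with an estimated correlation). Nuclear-encoded respiratory chain subunits (7 rose, 10 fell and 25 did not pass, or 7 and 10 adjusted over the list alone), glucose metabolism (9 rose, 5 fell and 12 did not pass, or 9 and 5 adjusted over the list alone) and the urea cycle and amino acid list (12 rose, 7 fell and 18 did not pass, or 15 and 7 adjusted over the list alone) were not called, at camera adjusted p = 0.427, 0.479 and 0.163. Their medians were -0.15, 0.14 and 0.27, of which that of glucose metabolism turned negative under other scalings, and the urea cycle list was called higher without control replicate 1 (camera adjusted p = 0.047). Among the lower genes the KEGG group of oxidative phosphorylation passed a one-sided Fisher exact test (41 of 114 genes beside 25.2 by chance, adjusted p = 0.0317), but not among falls of at least 2-fold (adjusted p = 1). The liver pyruvate kinase *Pklr* fell by 2.18. Large falls outside the lists were those of *Car3* (-4.18), *Cyp26a1*, a retinoic acid hydroxylase (-4.15), and *Apol7a* (-4.17).

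Among markers of pericentral hepatocytes, which lie around the central vein, 0 rose, 20 fell and 1 did not pass (0 and 20 adjusted over the list alone). Pericentral hepatocyte markers had a median log2 fold change of -2.58 (camera adjusted p = 2.5e-08, and adjusted p = 0.433 with an estimated correlation). The glutamate transporter *Slc1a2* fell from 7.325 ± 0.827 to 0.025 ± 0.0354 FPKM (log2 fold change -8.16, 1 of the APAP libraries at 0) and the dicarboxylate transporter *Slc13a3* changed by -7.79. Among markers of periportal hepatocytes 11 rose, 1 fell and 10 did not pass (12 and 1 adjusted over the list alone). Periportal hepatocyte markers had a median log2 fold change of 0.75 (camera adjusted p = 0.00237, and adjusted p = 0.433 with an estimated correlation), with *Apoa4* at 3.10 and *Mfsd2a* at 2.45. Markers of other cells moved beside these groups. Of the erythroid markers 5 rose, 0 fell and 1 did not pass (5 and 0 adjusted over the list alone). Erythroid markers had a median log2 fold change of 2.04 (camera adjusted p = 0.00228, and adjusted p = 0.433 with an estimated correlation), with *Hbb-bs* at 2.91. Monocyte markers (4 rose, 0 fell and 2 did not pass, or 4 and 0 adjusted over the list alone) included *Thbs1* at 5.36 and *Cd14* at 4.63. Monocyte markers had a median log2 fold change of 0.74 (camera adjusted p = 0.0415, and adjusted p = 0.433 with an estimated correlation). Of the stellate cell markers 8 rose, 0 fell and 6 did not pass (9 and 2 adjusted over the list alone). Stellate cell markers had a median log2 fold change of 0.62 (camera adjusted p = 0.0415, and adjusted p = 0.56 with an estimated correlation). Sinusoidal endothelial (5 rose, 1 fell and 12 did not pass, or 5 and 1 adjusted over the list alone), Kupffer cell (4 rose, 0 fell and 13 did not pass, or 1 and 0 adjusted over the list alone) and neutrophil markers (3 rose, 0 fell and 4 did not pass, or 3 and 0 adjusted over the list alone) had medians of 0.26, 0.36 and 1.57 and were not called, at camera adjusted p = 0.106, 0.0611 and 0.0556. Kupffer cell markers were called higher without control replicate 1 (0.047) or APAP replicate 1 (0.00364), and neutrophil markers without control replicate 1 (0.047) or APAP replicate 3 (0.0258). Without the filter on low values both were called higher as well (0.0169 and 0.00249).

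Few members of the remaining lists, apart from the clock genes described later, were measured above the filter. Of 9 cell cycle genes 2 rose, 3 fell and 4 did not pass (2 and 4 adjusted over the list alone). Cell cycle genes had a median of -0.26 (camera adjusted p = 0.479), with *Ccne1* at 2.25 and *Tk1* at -3.16. Of 5 cholangiocyte markers 2 rose, 1 fell and 2 did not pass (2 and 1 adjusted over the list alone). Cholangiocyte markers had a median of 0.45 (camera adjusted p = 0.537). Of 4 lymphocyte markers 1 rose, 0 fell and 3 did not pass (1 and 0 adjusted over the list alone). Lymphocyte markers had a median of -0.23 (camera adjusted p = 0.959), with a mean of 0.13. The neighbouring tissue list (1 rose, 0 fell and 2 did not pass, or 1 and 0 adjusted over the list alone) and the sex-linked list (1 rose, 0 fell and 1 did not pass, or 1 and 0 adjusted over the list alone) were too short for the test. *Fabp4* rose by 1.63, and the Y-linked *Ddx3y* by 1.01.

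Camera called 21 of 36 tested lists, 14 higher and 7 lower, and fry 27. None of camera's list calls in any of the 3 comparisons held with an estimated correlation, where the smallest adjusted p was 0.433 here. Left-out libraries ended the list calls of p53 targets, plasma proteins and stellate cell markers (without control replicate 3 or APAP replicate 1, adjusted p up to 0.0618, 0.0801 and 0.0951), cell death (without APAP replicate 1, 0.0823) and monocyte markers (without control replicate 3 or APAP replicate 3, 0.0612), and 34 of 128 called named genes lost their call at least once, among them *Sprr1a* (without control replicate 3 or APAP replicate 1, 0.0531).

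**Figure D2:**
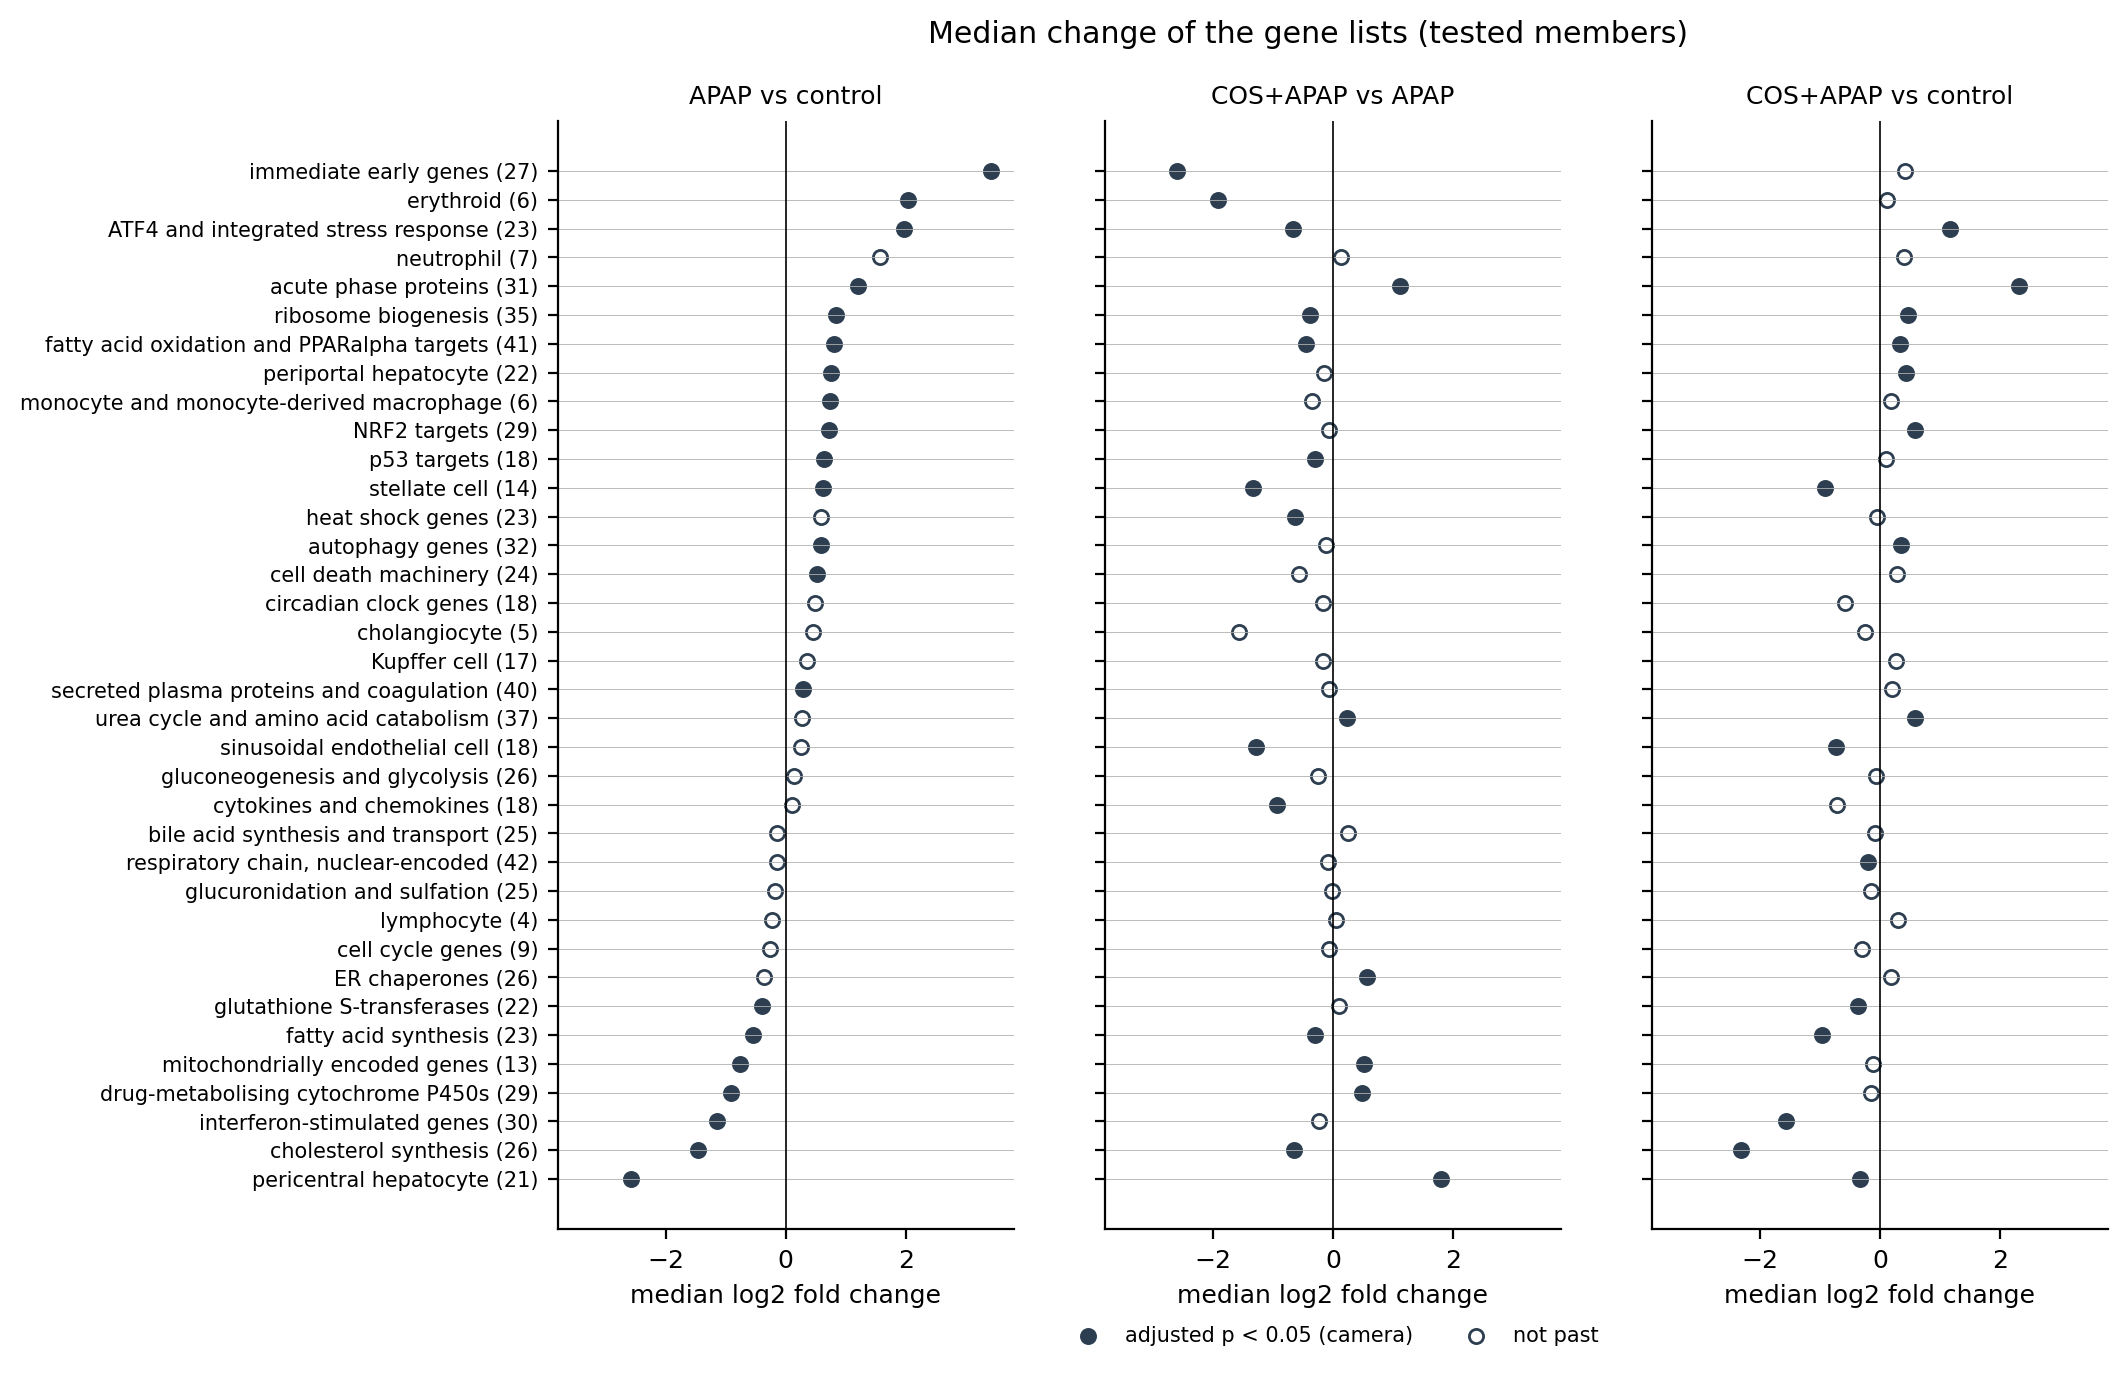
Median log2 fold change of the tested members of each fixed gene list in the 3 comparisons, with lists on the vertical axis (tested members in parentheses) and the log2 scale on the horizontal axis, filled points for a camera adjusted p below 0.05 and open points for the rest. Pericentral hepatocyte markers had a median of -2.58 after APAP and 1.81 with COS pretreatment against APAP, and immediate early genes 3.42 and -2.59.

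The comparison of COS+APAP with APAP asked how pretreated livers differed from livers given the toxic dose alone. No group received COS alone, so an effect of COS by itself cannot be separated from an effect on the response to APAP. In pretreated livers most immediate early genes fell, and most pericentral hepatocyte markers and acute phase proteins rose. *Fos*, an AP-1 subunit (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), went from 66.27 ± 10.7 FPKM in APAP to 0.47 ± 0 in COS+APAP (log2 fold change -7.10 ± 0.20, adjusted p = 0.000889), beside 2.05 ± 0.269 in control. *Saa2*, a serum amyloid A protein whose reads its near copy *Saa1* can share (ENSMUSG00000057465, chromosome 7, 46751790 to 46754313), rose from 10.8 ± 5.41 to 1611 ± 1070 FPKM (7.25 ± 0.71, adjusted p = 0.00617). *Cyp7a1* rose from 0.73 ± 0.283 to 30.89 ± 12.3 FPKM (5.42 ± 0.47, adjusted p = 0.00575). In all, 2249 genes changed, 1130 higher and 1119 lower, of which 530 and 584 differed at least 2-fold.

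Among the immediate early genes 1 rose, 19 fell and 7 did not pass (1 and 23 adjusted over the list alone). Immediate early genes had a median log2 fold change of -2.59 (camera adjusted p = 1.1e-10, and adjusted p = 0.541 with an estimated correlation). *Jun* (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222) dropped from 361 ± 29.3 to 10.3 ± 6.87 FPKM (-5.11 ± 0.58), *Egr1* fell by 6.20 and *Ier2* by 4.41. *Mir22* fell by 6.68 and *Hilpda*, a lipid droplet protein induced by hypoxia, by 4.71. Of the heat shock genes 0 rose, 8 fell and 15 did not pass (1 and 13 adjusted over the list alone). Heat shock genes had a median log2 fold change of -0.63 (camera adjusted p = 5.7e-05, and adjusted p = 0.592 with an estimated correlation), with *Hsp90aa1* at -2.04. In the ATF4 and integrated stress response list 1 rose, 7 fell and 15 did not pass (2 and 8 adjusted over the list alone). Genes of the integrated stress response had a median log2 fold change of -0.66 (camera adjusted p = 0.019, and adjusted p = 0.544 with an estimated correlation), but *Atf3* (-2.03, adjusted p = 0.169), *Ddit3* (-2.01, 0.142) and *Trib3* (-0.73, 0.111) did not pass the test. Of the p53 targets 2 rose, 5 fell and 11 did not pass (2 and 6 adjusted over the list alone). p53 targets had a median log2 fold change of -0.30 (camera adjusted p = 0.0475, and adjusted p = 0.541 with an estimated correlation). *Gdf15* fell by 4.02 and *Btg2* by 3.87, and *Cdkn1a* did not pass the test (-1.10, adjusted p = 0.249). Of the NRF2 targets 2 rose, 4 fell and 23 did not pass (4 and 8 adjusted over the list alone). NRF2 targets had a median of -0.06 (camera adjusted p = 0.408), with *Hmox1* at -2.54 and the biliverdin reductase *Blvrb* at 1.28, while *Nqo1* (0.02) and *Gclm* (0.64) did not pass.

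Among the acute phase proteins 19 rose, 3 fell and 9 did not pass (19 and 4 adjusted over the list alone). Acute phase proteins had a median log2 fold change of 1.12 (camera adjusted p = 4.25e-05, and adjusted p = 0.592 with an estimated correlation). *Saa1* rose by 5.26, *Lcn2* by 3.02 and *Orm2*, an acid glycoprotein, by 4.44, whereas *Serpina3g* fell by 3.18 and *Mt1* did not pass (-0.16, adjusted p = 0.507). Among the ER chaperones 13 rose, 1 fell and 12 did not pass (14 and 1 adjusted over the list alone). ER chaperones had a median log2 fold change of 0.57 (camera adjusted p = 0.000295, and adjusted p = 0.592 with an estimated correlation), with *Sdf2l1* at 2.30 against *Xbp1*, a transcription factor of the unfolded protein response, at -1.51. Of the cytokines and chemokines 1 rose, 8 fell and 9 did not pass (1 and 10 adjusted over the list alone). Cytokines and chemokines had a median log2 fold change of -0.93 (camera adjusted p = 0.0121, and adjusted p = 0.562 with an estimated correlation). Interferon-stimulated genes were not called (2 rose, 4 fell and 24 did not pass, or 2 and 4 adjusted over the list alone), and *Iigp1*, a GTPase of that list, fell by 2.67. Interferon-stimulated genes had a median of -0.23 (camera adjusted p = 0.15), but the list was called lower without APAP replicate 3 (0.00112, beside 0.963 without APAP replicate 1). In the cell death list 4 rose, 9 fell and 11 did not pass (5 and 11 adjusted over the list alone). Cell death genes had a median of -0.56 (camera adjusted p = 0.0747), called lower without APAP replicate 3 (0.0424) or COS+APAP replicate 2 (0.0487), with *Casp9* at -3.36.

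Among pericentral hepatocyte markers 17 rose, 0 fell and 4 did not pass (18 and 0 adjusted over the list alone). Pericentral hepatocyte markers had a median log2 fold change of 1.81 (camera adjusted p = 7.42e-09, and adjusted p = 0.541 with an estimated correlation). *Slc1a2* rose from 0.025 ± 0.0354 to 6.06 ± 2.22 FPKM (8.04) and *Slc13a3* by 7.87. Of the cytochrome P450s 11 rose, 1 fell and 17 did not pass (11 and 2 adjusted over the list alone). Cytochrome P450s had a median log2 fold change of 0.48 (camera adjusted p = 0.000804, and adjusted p = 0.592 with an estimated correlation). *Cyp2a5*, which is in both lists, rose by 4.61. *Cyp2e1* rose to 2519 ± 359 FPKM (1.35 ± 0.27, adjusted p = 0.0237), a call lost without any one of the 4 libraries compared (adjusted p up to 0.117). Periportal markers (2 rose, 6 fell and 14 did not pass, or 2 and 8 adjusted over the list alone) were not called, with the cadherin *Cdh1* at -2.81. Periportal hepatocyte markers had a median of -0.14 (camera adjusted p = 0.0726) and were called lower without COS+APAP replicate 3 (0.0227). Of the glutathione S-transferases 5 rose, 2 fell and 15 did not pass (7 and 3 adjusted over the list alone). Glutathione S-transferases had a median of 0.10 (camera adjusted p = 0.408), a median that changed sign under other scalings, with *Gstm2* at 2.70 and *Gstm3* at 2.43. In the urea cycle and amino acid list 7 rose, 0 fell and 30 did not pass (7 and 0 adjusted over the list alone). Urea cycle and amino acid genes had a median log2 fold change of 0.23 (camera adjusted p = 0.019, and adjusted p = 0.654 with an estimated correlation). Of the transcripts of the mitochondrial genome 4 rose, 0 fell and 9 did not pass (4 and 0 adjusted over the list alone). Mitochondrially encoded genes had a median log2 fold change of 0.52 (camera adjusted p = 0.000798, and adjusted p = 0.592 with an estimated correlation).

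Of the fatty acid oxidation genes 2 rose, 13 fell and 26 did not pass (2 and 16 adjusted over the list alone). Fatty acid oxidation genes had a median log2 fold change of -0.44 (camera adjusted p = 0.000632, and adjusted p = 0.592 with an estimated correlation), with the thioesterase *Acot3* at -3.59. Of the cholesterol synthesis genes 1 rose, 9 fell and 16 did not pass (1 and 12 adjusted over the list alone), with *Idi1*, the isopentenyl diphosphate isomerase, at -3.23. Cholesterol synthesis genes had a median log2 fold change of -0.65 (camera adjusted p = 0.000798, and adjusted p = 0.592 with an estimated correlation). Of the fatty acid synthesis genes 1 rose, 6 fell and 16 did not pass (1 and 6 adjusted over the list alone). Fatty acid synthesis genes had a median log2 fold change of -0.30 (camera adjusted p = 0.0121, and adjusted p = 0.541 with an estimated correlation). In ribosome biogenesis 0 rose, 7 fell and 28 did not pass (0 and 6 adjusted over the list alone). Ribosome biogenesis genes had a median log2 fold change of -0.38 (camera adjusted p = 0.000804, and adjusted p = 0.592 with an estimated correlation). Glucose metabolism was not called (2 rose, 6 fell and 18 did not pass, or 4 and 7 adjusted over the list alone), although *Pkm*, the pyruvate kinase of non-hepatocyte cells, fell by 2.18 and *Pfkfb1*, a hepatic regulator of glycolysis, rose by 1.59. Glucose metabolism genes had a median of -0.24 (camera adjusted p = 0.339).

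Markers of several other liver cells were lower in the same libraries. Of the sinusoidal endothelial markers 1 rose, 12 fell and 5 did not pass (1 and 15 adjusted over the list alone). Sinusoidal endothelial cell markers had a median log2 fold change of -1.28 (camera adjusted p = 3.83e-06, and adjusted p = 0.541 with an estimated correlation), with the endothelial cadherin *Cdh5* at -1.92. Of the stellate cell markers 0 rose, 11 fell and 3 did not pass (1 and 12 adjusted over the list alone). Stellate cell markers had a median log2 fold change of -1.33 (camera adjusted p = 3.83e-06, and adjusted p = 0.541 with an estimated correlation). Of the erythroid markers 0 rose, 5 fell and 1 did not pass (0 and 5 adjusted over the list alone). Erythroid markers had a median log2 fold change of -1.92 (camera adjusted p = 0.00015, and adjusted p = 0.541 with an estimated correlation), with *Hbb-bt* at -2.27. Monocyte markers (0 rose, 2 fell and 4 did not pass, or 0 and 2 adjusted over the list alone) included *Thbs1*, a matrix protein also made by other cells, at -6.48. Monocyte markers had a median of -0.35 (camera adjusted p = 0.0747) and were called lower without APAP replicate 1 (0.0352). Kupffer cell (1 rose, 1 fell and 15 did not pass, or 0 and 0 adjusted over the list alone) and neutrophil markers (0 rose, 1 fell and 6 did not pass, or 0 and 1 adjusted over the list alone) were not called. Kupffer cell markers had a median of -0.16 (camera adjusted p = 0.566), were called lower without APAP replicate 1 (0.0377) and turned to higher without APAP replicate 3 (0.541). Neutrophil markers had a median of 0.13 (camera adjusted p = 0.737), against a mean of -0.99. Among the lower genes, 208 of 2331 Gene Ontology terms passed a one-sided Fisher exact test with Benjamini-Hochberg adjustment. These included cell adhesion with 58 of 156 genes beside 19.1 by chance (adjusted p = 1.52e-12) and extracellular matrix with 27 of 56 beside 6.9 (adjusted p = 2.87e-08). Among the higher genes 1 term passed, protein N-linked glycosylation with 15 of 34 genes beside 4.0 (adjusted p = 0.00438), beside 72 at an unadjusted p under 0.05. That term did not pass among rises of at least 2-fold (adjusted p = 0.576). The Fisher test treats genes as independent draws, and the terms were not tested again with a library left out.

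Camera called 18 lists, 6 higher and 12 lower (0 with an estimated correlation, smallest adjusted p = 0.541), and the lists not named were not called, of which respiratory chain subunits were called lower without COS+APAP replicate 2 (camera adjusted p = 0.0329). Fry did not call heat shock genes and ribosome biogenesis (0.0605 for each), mitochondrially encoded genes (0.0735), fatty acid oxidation and cholesterol synthesis (0.0927 for each) or the urea cycle list (0.118). For glucuronidation and sulfation genes (3 rose, 1 fell and 21 did not pass, or 3 and 1 adjusted over the list alone) camera's direction, higher, and the mean of 0.01 opposed the median of -0.02, and for cell cycle genes the mean (0.01) opposed the median (-0.07). Camera's direction turned for the former without APAP replicate 1 (0.853) and for the latter without APAP replicate 3 (0.958). The count of changed genes was 644 without APAP replicate 1, 1297 without APAP replicate 3, 612 without COS+APAP replicate 2 and 726 without COS+APAP replicate 3, list calls ended for p53 targets (without APAP replicate 3 or COS+APAP replicate 3, adjusted p up to 0.0781) and the urea cycle (without COS+APAP replicate 3, 0.0781), and 77 of 116 called named genes lost their call at least once, among them *Egr1* (without APAP replicate 1, 0.0652) and *Hilpda* (without either COS+APAP library, up to 0.067). The COS+APAP libraries carry another title prefix than the other 4, so that COS and a batch cannot be told apart for any of these differences, the attribution of the acute phase difference to COS is in doubt, and an exchange of the APAP and COS+APAP labels, as the protocol text would have it, would turn every sign of this comparison.

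**Figure D3:**
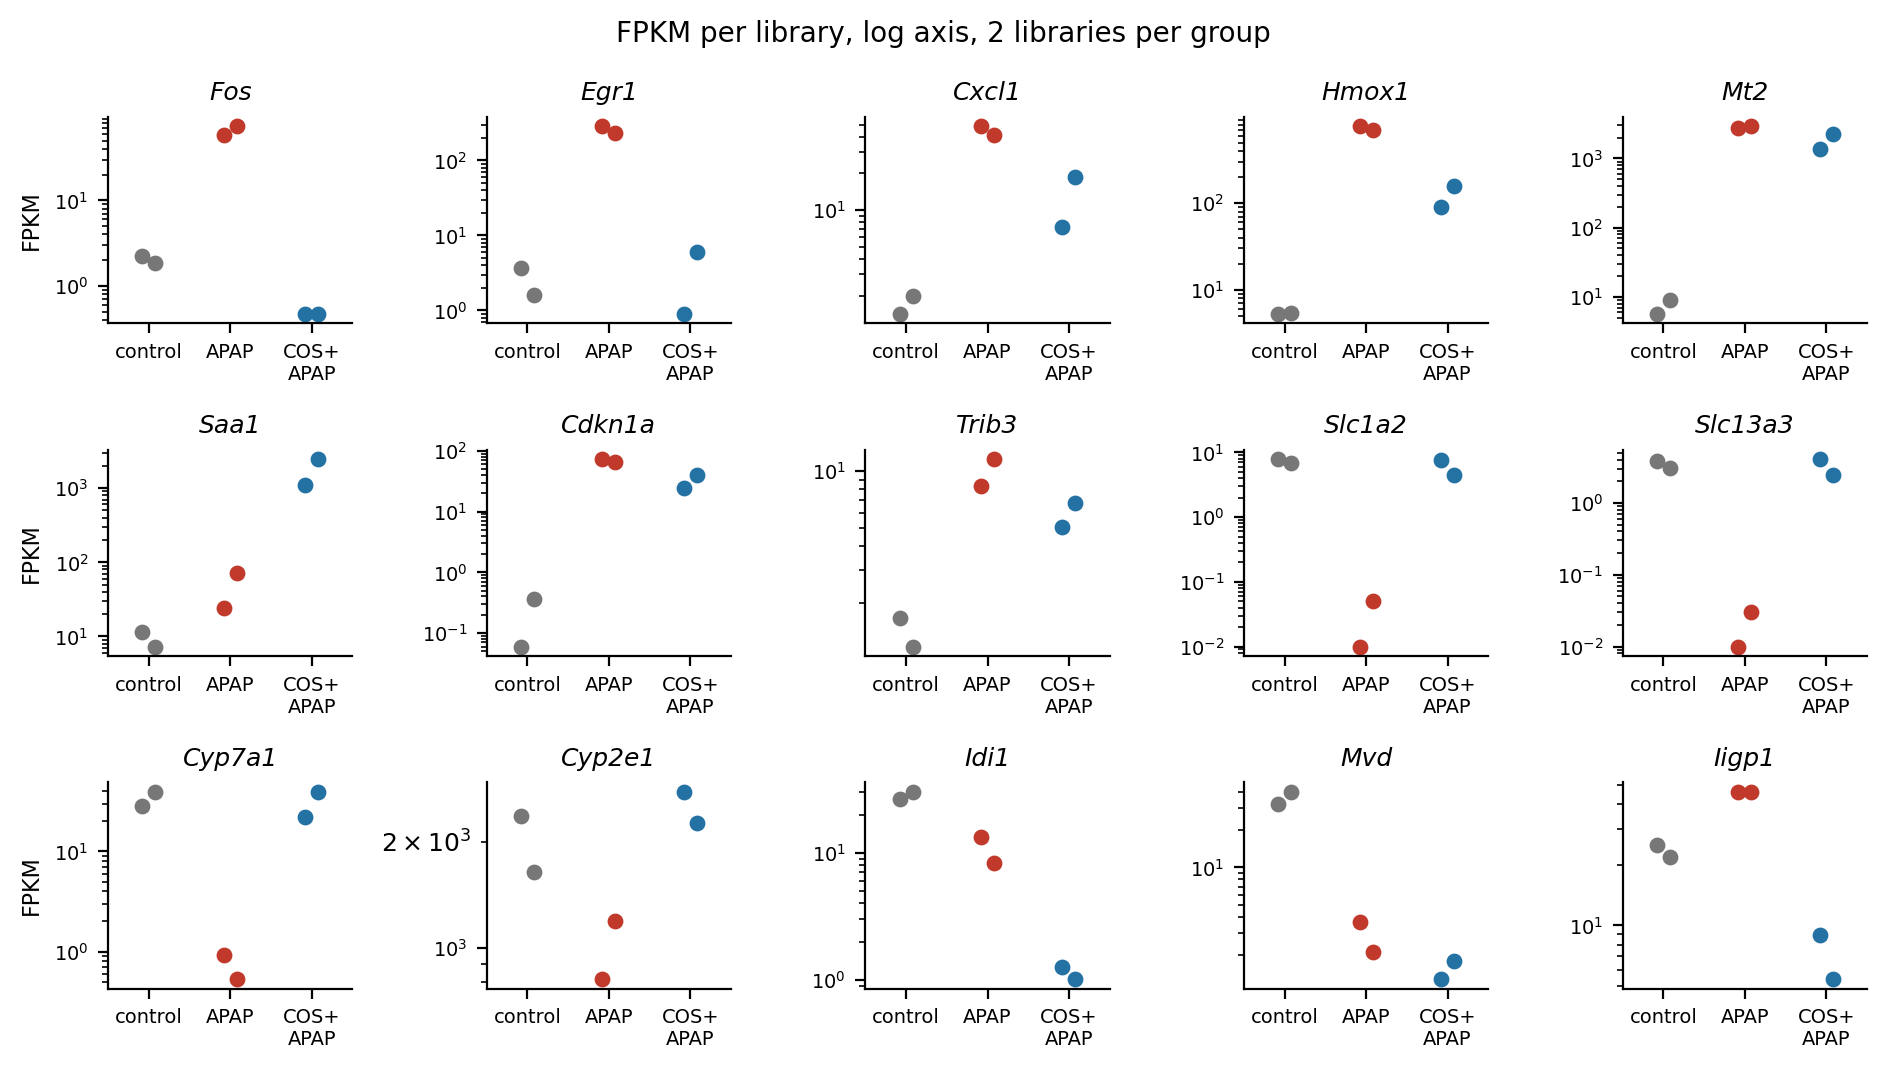
FPKM of named genes per library on a log axis, with 2 libraries in each group as points and values under 0.01 drawn at 0.01. *Fos* stood at 66.3 ± 10.7 in APAP against 2.05 ± 0.269 in control and 0.47 in COS+APAP, and *Cyp7a1* at 0.73 ± 0.283 in APAP against 33.8 ± 7.23 and 30.9 ± 12.3 (mean ± SD, n = 2).

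The combination of both effects asked how far genes changed by APAP lay nearer to control in pretreated livers. Of 1795 genes called in both comparisons, 1719 moved in opposite directions and 76 in the same direction, counts that the shared APAP libraries tilt towards opposite directions. With a different APAP library in each effect, 498 genes were opposed and 21 were not (APAP replicate 1 in the APAP effect), or 802 and 61 (APAP replicate 3), where independent lists would share 110.1 and 109.8, or 196.5 and 196.3. *Fos*, *Egr1* and *Jun* were among the 900 genes that rose after APAP and were lower with COS, and *Cyp7a1*, *Slc1a2*, *Slc13a3* and *Cyp2a5* among the 819 that fell and were higher. *Saa1*, *Lcn2* and *Plin4* rose after APAP and were higher again with COS, as 45 genes did, while *Idi1* and *Car3* were among 31 that fell and were lower again. Of these genes, calls after APAP were lost for *Saa1* without control replicate 1, control replicate 3 or APAP replicate 3 (adjusted p up to 0.124) and for *Idi1* without control replicate 3 (0.0623), and calls with COS for *Car3* without APAP replicate 1 or either COS+APAP library (up to 0.192) and for *Egr1* without APAP replicate 1 (0.0652). Genes that had risen after APAP (2342) had a median log2 fold change against control of 1.02 in APAP and 0.50 in COS+APAP, and 829 of them were still called higher than control. Genes that had fallen (2219) had medians of -0.99 and -0.48, and 803 were still called lower. The counts of 829 and 803 rest on the same control libraries that helped to choose the genes, which tilts them upwards. In COS+APAP, 87.8% of the risen and 87.1% of the fallen genes lay nearer to control than in APAP. The genes were chosen on the same APAP libraries, which tilts these shares upwards and enlarges the APAP medians. With genes chosen without APAP replicate 1 or 3, 83.1% and 85.9% lay nearer to control than in the left-out library. Across the 10051 genes the effects correlated at r = -0.676. Because both effects share the APAP libraries, draws with no effect gave -0.499 on average, the lowest of 100 being -0.589. The covariance was -0.782 beside a simulated -0.069, a difference of -0.713. With one APAP library for each effect r was -0.58 and -0.508. The count of opposed genes fell to 509, 1024, 467 and 600 without APAP replicate 1, APAP replicate 3, COS+APAP replicate 2 and COS+APAP replicate 3.

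**Figure D4:**
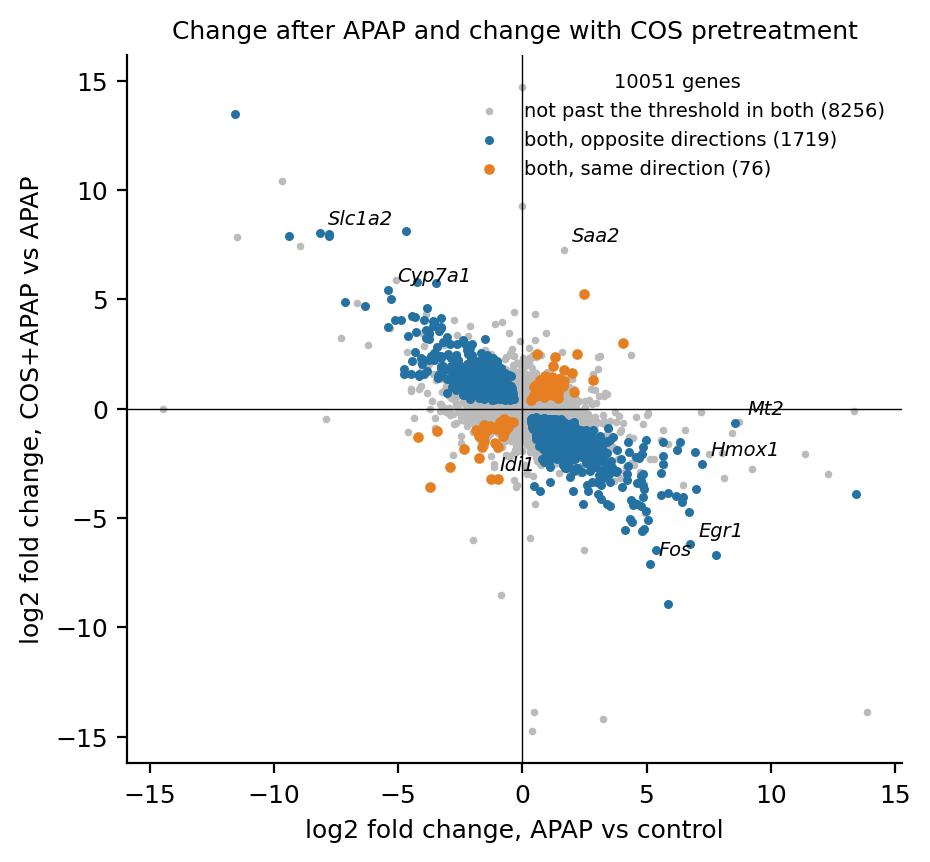
Log2 fold change of each tested gene after APAP against control (horizontal) and of COS+APAP against APAP (vertical), 1 point per gene, with genes called in both comparisons marked by direction. Of 1795 genes called in both, 1719 lay in the quadrants of opposite direction, part of the slope (r = -0.676) comes from the shared APAP libraries, and the far folds of genes at 0 in a group depend on the prior count.

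The comparison of COS+APAP with control asked how pretreated livers given APAP differed from untreated livers. The title prefix separates these groups too, so a batch cannot be told apart from the treatment. If the APAP and COS+APAP labels were exchanged, this would be APAP alone against control. Some median log2 fold changes of lists lay further from control than after APAP alone (acute phase proteins 2.32 beside 1.21, cholesterol synthesis -2.31 beside -1.47). Others lay nearer (pericentral markers -0.33 beside -2.58). Most acute phase proteins and genes of the integrated stress response rose, and most cholesterol synthesis and interferon-stimulated genes fell. *Saa1* (ENSMUSG00000074115, chromosome 7, 46740497 to 46742980) stood at 9.39 ± 2.93 FPKM in control and 1782 ± 971 in COS+APAP (log2 fold change 7.73 ± 0.82, adjusted p = 0.00548). *Lcn2* (ENSMUSG00000026822, chromosome 2, 32384633 to 32387797) rose from 3.25 ± 0.127 to 395.4 ± 24.2 FPKM (7.08 ± 0.55, adjusted p = 0.00336). *Car3*, a carbonic anhydrase (ENSMUSG00000027559, chromosome 3, 14863512 to 14872523), fell from 736 ± 53.1 to 15 ± 3.13 FPKM (-5.46 ± 0.41, adjusted p = 0.00304). There were 2109 changed genes, 1073 higher and 1036 lower, of which 481 and 507 differed at least 2-fold.

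Of the acute phase proteins 26 rose, 0 fell and 5 did not pass (28 and 0 adjusted over the list alone). Acute phase proteins had a median log2 fold change of 2.32 (camera adjusted p = 3.18e-18, and adjusted p = 0.51 with an estimated correlation), with *Saa2* at 8.93 and *Mt2* at 8.09. In the ATF4 and integrated stress response list 14 rose, 1 fell and 8 did not pass (17 and 2 adjusted over the list alone), with *Psat1* at 4.84 and *Trib3* at 2.21. Genes of the integrated stress response had a median log2 fold change of 1.17 (camera adjusted p = 1.53e-06, and adjusted p = 0.415 with an estimated correlation). NRF2 targets were also called higher (10 rose, 1 fell and 18 did not pass, or 11 and 2 adjusted over the list alone), with *Hmox1* at 4.70, the carbonyl reductase *Cbr3* at 3.27, *Gclc* at 1.88 and *Nqo1* at 1.15. NRF2 targets had a median log2 fold change of 0.58 (camera adjusted p = 0.00366, and adjusted p = 0.415 with an estimated correlation). *Cdkn1a* rose by 7.36, although p53 targets were not called (3 rose, 0 fell and 15 did not pass, or 4 and 0 adjusted over the list alone). p53 targets had a median of 0.10 (camera adjusted p = 0.477), a median that changed sign under other scalings. Immediate early genes were not called either (5 rose, 2 fell and 20 did not pass, or 7 and 4 adjusted over the list alone), and *Fos* lay below control (-1.96). Immediate early genes had a median of 0.42 (camera adjusted p = 0.564), a median that stayed at 0.42 with *Fosl1* at its bound. Without COS+APAP replicate 2 they were called higher (0.00121), and without COS+APAP replicate 3 camera's direction turned to lower (0.194). Autophagy genes were called higher (11 rose, 1 fell and 20 did not pass, or 13 and 1 adjusted over the list alone), with *Ctsl* at 2.22 and *Sqstm1* at 1.90. Autophagy genes had a median log2 fold change of 0.36 (camera adjusted p = 0.000107, and adjusted p = 0.578 with an estimated correlation). In ribosome biogenesis 10 rose, 0 fell and 25 did not pass (17 and 0 adjusted over the list alone). Ribosome biogenesis genes had a median log2 fold change of 0.47 (camera adjusted p = 6.81e-06, and adjusted p = 0.578 with an estimated correlation). Of the heat shock genes 2 rose, 8 fell and 13 did not pass (3 and 8 adjusted over the list alone). Heat shock genes had a median of -0.04 (camera adjusted p = 0.186), a median that changed sign under other scalings, with a mean of 0.12, and *Fkbp4* fell by 2.01. They were called lower without COS+APAP replicate 3 (0.0114).

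Among cholesterol synthesis genes 0 rose, 22 fell and 4 did not pass (0 and 25 adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of -2.31 (camera adjusted p = 3.48e-16, and adjusted p = 0.51 with an estimated correlation). *Idi1* went from 28.39 ± 2.73 to 1.14 ± 0.184 FPKM (-4.48), and *Mvd* fell by 4.41. Of the fatty acid synthesis genes 2 rose, 13 fell and 8 did not pass (3 and 13 adjusted over the list alone), with *Thrsp* at -2.93. Fatty acid synthesis genes had a median log2 fold change of -0.96 (camera adjusted p = 2.39e-06, and adjusted p = 0.397 with an estimated correlation). Among interferon-stimulated genes 0 rose, 21 fell and 9 did not pass (0 and 25 adjusted over the list alone). Interferon-stimulated genes had a median log2 fold change of -1.56 (camera adjusted p = 1.93e-12, and adjusted p = 0.534 with an estimated correlation), with *Isg15* at -3.24. Of the fatty acid oxidation genes 14 rose, 4 fell and 23 did not pass (16 and 5 adjusted over the list alone). Fatty acid oxidation genes had a median log2 fold change of 0.33 (camera adjusted p = 0.013, and adjusted p = 0.766 with an estimated correlation), with *Cidec* at 5.00 and *Acot3* at -3.84. The urea cycle and amino acid list was called higher (17 rose, 2 fell and 18 did not pass, or 18 and 3 adjusted over the list alone), with the mitochondrial glutamate carrier *Slc25a22* at 2.23. Urea cycle and amino acid genes had a median log2 fold change of 0.58 (camera adjusted p = 0.00248, and adjusted p = 0.651 with an estimated correlation). *Hsd3b5*, a steroid reductase of male mouse liver, fell by 4.91, and *Inmt*, an amine methyltransferase, fell by 4.46.

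Of the pericentral hepatocyte markers 0 rose, 6 fell and 15 did not pass (0 and 6 adjusted over the list alone). Pericentral hepatocyte markers had a median log2 fold change of -0.33 (camera adjusted p = 0.0476, and adjusted p = 0.766 with an estimated correlation), a call lost with median-ratio scaling (0.0502). Of the periportal hepatocyte markers 8 rose, 2 fell and 12 did not pass (11 and 3 adjusted over the list alone). Periportal hepatocyte markers had a median log2 fold change of 0.43 (camera adjusted p = 0.0438, and adjusted p = 0.578 with an estimated correlation). *Cyp2e1* (0.49, adjusted p = 0.244), *Cyp7a1* (0.03, 0.964) and *Alb* (0.06, 0.884) did not pass the test, and the small values of *Cyp7a1* and *Alb* turned negative under other scalings. Of the cytochrome P450s 2 rose, 7 fell and 20 did not pass (2 and 7 adjusted over the list alone). Cytochrome P450s had a median of -0.15 (camera adjusted p = 0.212), with *Cyp3a13* at 2.25, and were called lower without control replicate 3 (0.0331). Among the genes lower than control the KEGG group of drug metabolism by cytochrome P450 passed a one-sided Fisher exact test (15 of 47 genes beside 5.6 by chance, adjusted p = 0.013), as did those of retinol metabolism (18 of 59 beside 7.0) and chemical carcinogenesis (18 of 62 beside 7.4) at the same adjusted p. Among falls of at least 2-fold only chemical carcinogenesis passed of these groups (adjusted p = 0.0201, beside 0.213 for drug metabolism and 0.149 for retinol metabolism). Glutathione S-transferases were called lower (1 rose, 5 fell and 16 did not pass, or 2 and 5 adjusted over the list alone), with *Gsta3* at -2.47 and *Mgst3* at -2.71. Glutathione S-transferases had a median log2 fold change of -0.36 (camera adjusted p = 0.0476, and adjusted p = 0.51 with an estimated correlation), a call lost with median-ratio scaling (0.0502). Of the nuclear-encoded respiratory chain subunits 0 rose, 2 fell and 40 did not pass (0 and 0 adjusted over the list alone). Respiratory chain subunits had a median log2 fold change of -0.20 (camera adjusted p = 0.00795, and adjusted p = 0.578 with an estimated correlation). Of the sinusoidal endothelial markers 1 rose, 9 fell and 8 did not pass (1 and 11 adjusted over the list alone), with the endothelial receptors *Gpr182* at -1.43 and *Stab1* at 1.34. Sinusoidal endothelial cell markers had a median log2 fold change of -0.73 (camera adjusted p = 0.00261, and adjusted p = 0.534 with an estimated correlation). Of the stellate cell markers 0 rose, 6 fell and 8 did not pass (0 and 8 adjusted over the list alone). Stellate cell markers had a median log2 fold change of -0.92 (camera adjusted p = 0.000254, and adjusted p = 0.534 with an estimated correlation). Erythroid markers were not called (0 rose, 0 fell and 6 did not pass, or 0 and 0 adjusted over the list alone), and neither were Kupffer cell markers (2 rose, 0 fell and 15 did not pass, or 2 and 0 adjusted over the list alone), of which the scavenger receptor *Marco* rose by 1.62. Erythroid markers had a median of 0.12 (camera adjusted p = 0.475), a median that changed sign under other scalings. Kupffer cell markers had a median of 0.27 (camera adjusted p = 0.218).

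Camera called 16 lists, 8 higher and 8 lower (0 with an estimated correlation, smallest adjusted p = 0.397), and the lists not named were not called, of which plasma proteins were called higher without control replicate 1 (camera adjusted p = 0.0127). Fry did not call pericentral markers (0.216), fatty acid oxidation or the respiratory chain (0.0819 for each). By fry alone, cell cycle (adjusted p = 0.0117) and clock genes (0.033) were called lower and p53 targets higher (0.027). Median and mean differed in sign for glucuronidation and sulfation genes (-0.15 and 0.04), and for glucose metabolism camera's direction, higher, opposed the median of -0.06. The direction of the former turned without control replicate 1 (0.851), that of glucose metabolism without control replicate 3 (0.526) or COS+APAP replicate 2 (0.683), that of cytokines and of cholangiocyte markers without COS+APAP replicate 2 (0.958 for each), and that of mitochondrially encoded genes without control replicate 3 (0.925). The number of changed genes was 1211 without control replicate 1, 732 without control replicate 3, 938 without COS+APAP replicate 2 and 590 without COS+APAP replicate 3, 64 of 111 called named genes lost their call at least once, and list calls ended for glutathione S-transferases and periportal markers (without control replicate 3 or COS+APAP replicate 3, adjusted p up to 0.085 and 0.131), pericentral markers (without control replicate 1 or COS+APAP replicate 3, 0.135), fatty acid oxidation (without COS+APAP replicate 2, 0.274) and the respiratory chain (without COS+APAP replicate 3, 0.0954).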

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

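Limma on log2(FPKM + 1) was the planned main test for a table without counts and became an alternative once counts were found. Chosen after seeing the data were library totals without TMM, DESeq2, counts divided by 4 and the left-out libraries for list and opposed counts. So were a different APAP library in each effect for opposed counts and the fold threshold for terms. Beside the 4561, 2249 and 2109 changed genes of APAP against control, COS+APAP against APAP and COS+APAP against control, a mean FPKM of at least 5 gave 2301, 1093 and 1295, with fewer genes tested (4488), and 836 opposed genes. The threshold of at least 2-fold, a subset by construction, gave 2301, 1114 and 988. DESeq2 gave 3552 for COS+APAP against APAP and 3421 for COS+APAP against control. The cause was not tested. Leaving out each library in turn gave 3044 to 3577, 612 to 1297 and 590 to 1211 changed genes and 467 to 1292 opposed genes (498 and 802 with a different APAP library in each effect), where the lone library of a group was assumed to vary like the others. Called lists then numbered 17 to 24, 17 to 20 and 13 to 16. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 27, 17 and 16, of which 21, 12 and 13 were among camera's 21, 18 and 16. For COS+APAP against control, pericentral markers and glutathione S-transferases lost their call with median-ratio scaling (adjusted p = 0.0502 for both) and on log2(FPKM + 0.1) values (0.178 and 0.0631), and periportal markers (0.181) and respiratory chain subunits (0.0792) with quantile normalization. For APAP against control, plasma proteins lost it with quantile normalization (0.147) and monocyte markers without the filter (0.0604). Neutrophil markers gained a call there with fry (0.0258), on log2(FPKM + 0.1) values (0.0305), after quantile normalization (0.0496) and without the filter (0.00249), and Kupffer cell markers (0.0169) and cytokines (0.00795) without the filter. Also without the filter, calls as lower were gained in COS+APAP against APAP by markers of cholangiocytes (0.000424), neutrophils (0.0165) and periportal hepatocytes (0.0376), cell death (0.0101) and interferon-stimulated genes (0.0338), and against control by cholangiocyte markers (0.00483) and cytochrome P450s (0.0321), with plasma proteins called higher (0.0233). Fry gained 6, 5 and 3 lists. Called genes of at least 2-fold alone gave 97, 217 and 30 annotation terms beside 119, 240 and 40, with 33, 139 and 23 shared.

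The median against control of risen and fallen genes in COS+APAP, 0.50 and -0.48, was 0.4 and -0.55 with limma at a pseudocount of 0.1, which changes test, pseudocount and scaling together, and 0.38 and -0.38 after quantile normalization. With genes chosen without APAP replicate 1 it was 0.61 and -0.60, beside 1.21 and -1.20 in that library, and without APAP replicate 3 it was 0.55 and -0.53, beside 1.10 and -1.07, where the genes of all libraries stood at 1.02 and -0.99 in APAP. The correlation of effects was -0.58 and -0.508 with one APAP library for each. The cause of these shifts was not tested.

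Some alternatives moved the split of calls. Higher genes were 51.3%, 50.2% and 50.9% of the changed genes in the 3 comparisons, 51.2%, 48.8% and 49.2% with median-ratio scaling and 47.6%, 53.3% and 46.4% after quantile normalization, against 40.7%, 46.2% and 29.4% with limma on log2(FPKM + 1) and 40.4%, 47.8% and 30.5% with a pseudocount of 0.1, which change test, transformation and scaling together, 54.0%, 35.4% and 39.0% after scaling to one FPKM total, and 40.0%, 46.3% and 30.4% with library totals without TMM. Library totals moved the median of all genes to -0.153 for APAP against control and -0.154 for COS+APAP against control, limma on log2(FPKM + 1) to -0.103 and -0.107, and the FPKM total to -0.11 for COS+APAP against APAP, so small changes are relative to these.

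Named genes that reversed did not pass the test. For COS+APAP against control these were *Ddx3y* (-0.007 with limma on log2(FPKM + 1), -0.008 with a pseudocount of 0.1, -0.022 with library totals), *Alb* (-0.102, -0.102 and -0.117, and -0.03 with the FPKM total) and *Cyp7a1* (-0.167, -0.173 and -0.146, and -0.047). For COS+APAP against APAP *Nqo1* was -0.091 with the FPKM total. With left-out libraries the ranges were -0.459 to 0.394 for *Cyp7a1* and -1.687 to 0.466 for *Gclm* (COS+APAP against control), -1.436 to 0.431 for *Il1b* (APAP against control), and -0.808 to 1.344 for *Gclm*, -0.347 to 0.012 for *Mt1* and -0.023 to 0.068 for *Nqo1* (COS+APAP against APAP). The cause was not tested. Of the 378 values of named genes, 47 lost their call without the filter, 36 with only the 2 groups compared, 22 with quantile normalization, 1 with median-ratio scaling and 0 with DESeq2.

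For APAP against control a replicate block of numbers 1 and 3 gave 3187 changed genes (1709 higher, 1478 lower) with 1 residual degree of freedom. The differences between numbers 1 and 3 in control and APAP correlated at 0.022 across genes, so the numbers were not taken to pair the libraries. No paired analysis was possible for the comparisons with COS+APAP because its replicate numbers 2 and 3 share fewer than 2 numbers with the other groups. Simulated 2-fold changes were recovered in 28%, 26% and 10% of 50 genes at 2 libraries per group, and the part of depth in this was not tested. Far fewer genes were changed there than were called in the data, so these shares do not give the recovery in the data. Depth limits the folds of genes listed at 0 to bounds.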

Other observations

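Tests of a shift unrelated to APAP, of a batch in which APAP acted less, of COS acting on the response and of dilution of hepatocyte RNA were chosen after the result was seen, and the choice of the *Septin2* models followed from their values. Clock genes, not described above, were called by camera in no comparison. Camera looks for a shift of a list in one direction, so members that move in opposite directions offset each other. The missing call therefore does not show an unchanged clock. After APAP 6 rose, 5 fell and 7 did not pass (8 and 5 adjusted over the list alone), with a median of 0.48 against a mean of -0.30 (camera adjusted p = 0.589, fry in the opposite direction at 0.564). *Arntl*, an activator of the clock, rose by 2.80, while its outputs *Dbp* and *Per3* fell by 4.09 and 4.78. With COS pretreatment against APAP, 4 rose, 5 fell and 9 did not pass (5 and 6 adjusted over the list alone) (camera adjusted p = 0.566, fry lower at 0.0467), with the repressor *Nr1d1* at -2.46 and *Wee1* at -2.30. Against control, 4 rose, 7 fell and 7 did not pass (5 and 8 adjusted over the list alone) (camera adjusted p = 0.306, fry lower at 0.033), with *Per3* at -3.18 and *Hlf* at 1.86.

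Annotation terms gave further groups, of which protein processing in the endoplasmic reticulum and the response to interferon beta overlap in subject with the fixed lists. After APAP, 32 of 60 genes of the mitochondrial large ribosomal subunit fell beside 13.7 by chance (one-sided Fisher exact test, adjusted p = 0.000597), and 11 of 12 genes of NAD biosynthesis beside 2.7 (adjusted p = 0.000948). Among the rises, 10 of 11 genes of the inactivation of MAPK activity were called beside 2.8 by chance (adjusted p = 0.00293). In COS+APAP against APAP, where 12 of 18 sinusoidal endothelial and 11 of 14 stellate cell markers fell, focal adhesion genes were lower (38 of 97 beside 13.8, adjusted p = 2.19e-07), as were stress fiber genes (23 of 48 beside 5.9, adjusted p = 4.8e-07), and genes of protein processing in the endoplasmic reticulum were higher (34 of 142 beside 15.3, adjusted p = 0.00103). In COS+APAP against control, scavenger receptor genes were higher (11 of 19 beside 2.2, adjusted p = 0.00202) and genes of the response to interferon beta lower (15 of 28 beside 3.1, adjusted p = 1.18e-05). With called genes of at least 2-fold alone, the terms of the mitochondrial ribosome (adjusted p = 1), NAD biosynthesis (0.293), protein processing (1) and scavenger receptors (0.0621) did not pass, and those of MAPK inactivation (0.00177), focal adhesion (0.000604), stress fibers (9.54e-05) and interferon beta (1.78e-06) did.

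The opposition of the COS effect to the APAP effect was weighed first. Noise of the shared APAP libraries would bring the correlation near 0 with one APAP library for each effect, and it stayed at -0.508 or below. A shift that goes with the title prefix and has no relation to APAP was tested as the whole cause. Such a shift would bring no more than 1 in 2 of the APAP-changed genes nearer to control than in a left-out APAP library. At least 83.1% lay nearer. A shift as part of the cause, or one that falls on APAP-changed genes, was not tested. COS acting on the response and a batch in which the same dose acted less cannot be told apart, since 0 title prefixes were shared between the APAP and COS+APAP libraries. Both remain candidate explanations, as does an exchange of labels between these groups, which was not tested. An effect of COS that does not depend on APAP also stays open, because no group received COS alone.

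Pericentral markers were lower after APAP and higher with COS. Dilution of hepatocyte RNA by other cells would lower periportal markers as well, whose median was 0.75 higher after APAP. Scaling between libraries left at least 19 of the 21 tested pericentral markers past the threshold as falls. Loss of the cells next to the central vein would lower *Glul*, made in the innermost cells, at least as much as the wider-zoned *Cyp2e1*, and *Glul* changed by -1.71 ± 0.40 more on the log2 scale (-2.58 against -0.87). Loss of these cells may therefore contribute, and lower transcription in surviving cells stays open, as the same values would follow from it.

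Some folds were very large. Of 80 called genes with an absolute log2 fold change over 5, 18 (22.5%) overlapped another gene on the same strand, as did 1098 of 5130 other called genes (21.4%, one-sided Fisher exact p = 0.45), a test that cannot exclude shared reads in single genes, so the bound set beforehand, a p over 0.05, was too weak. A *Septin2* model, ENSMUSG00000116048, was at 0 FPKM in all 4 control and APAP libraries and at 10.35 and 13.1 in COS+APAP, while the other model, ENSMUSG00000026276, went from 3.97 and 3.88 in APAP to 0.65 and 0.16. The summed counts of both models differed by 0.43 on the log2 scale between COS+APAP and APAP, though their summed FPKM differed by 1.63, so a move of reads between models may account for the count of the first. This all-or-none difference follows the title prefix as well as COS, and its attribution to COS is in doubt, since a batch and COS cannot be told apart for it.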
